A study of Canis lupus familiaris with 48 samples.

How the data were processed

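The series holds 48 single-read RNA sequencing libraries of MDCK I cells, an established canine kidney epithelial cell line, in 4 groups of 12. Per the labels' protocols, cells were grown for 144 h and spent the last 24 h in regular medium (control, 300 mOsm) or in medium with 200 mOsm of added NaCl, raffinose or urea (500 mOsm in all). Polyadenylated RNA was made into libraries with the TruSeq RNA kit, version 2, which does not mark the strand. The number in each library's title is also its cell passage label; the same 12 passage numbers, from 1 to 19, occur in every group. The table's 4 columns of passage 10 carry an added number whose meaning the sources used here do not give, and they were matched to the libraries of passage 10.

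The authors deposited a table of raw read counts per gene for all 48 libraries. Per the submitters' processing notes, CASAVA, HISAT2 version 2.0.5 and featureCounts version 1.5.1 were used, and per the file headers reads were counted over exons, summed by gene, without strand, on the Ensembl release 87 annotation of the dog genome build CanFam3.1. The recorded counting command has no option for reads that match several places or several genes. Genes that overlap or have a near-identical copy are therefore measured with less certainty, and a gene and an antisense partner cannot be told apart. The table has 32704 genes, of which 25518 had a read in any library; 0 rows were blank or summary rows, and 0 columns of values were left unused.

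The genes carry Ensembl identifiers and no symbols. The table of gene names used here is of another assembly, UU_Cfam_GSD_1.0, and lists no Ensembl identifiers, so 0 of the 32704 identifiers could be paired with a symbol. The prepared lists of transporters, osmolyte genes, pathways and cell markers, and the rule that names genes by symbol, were therefore not applied, and transporters by name were not analysed here. In their place, chosen after the table was opened, stand groups taken from the annotation in the table: chromosomes, the mitochondrial genome, genes of a single exon, genes grouped by span, and runs of neighbouring genes.

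Library totals ran from 3.92 to 16.16 megareads (M) with a median of 10.51 M, so a gene at 1 count per M reads (CPM) had between 3.92 and 16.16 reads in a library. A count of 0 allows up to 3 reads, and such limits cover counting error only, since reads carry no molecular identifiers. Every library pair of a group differed by more than sampling noise: the lowest chi-square per gene was 5.27, so each library was counted as 1 replicate. The replicates are passages of 1 cell line, and p-values measure the spread between them.

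The counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (12654 genes), scaled by TMM factors, and fitted with glmQLFit over all 48 libraries with a term for the group. Each pair of groups was compared with glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM-scaled totals, and the standard error of a log2 fold change was its size over the square root of F. The common biological coefficient of variation was 17%. A linear term for passage, per 10 passages, and the solute by passage terms were tested in the same way. Passage numbers pair the libraries across groups, since the labels give the same passage to 4 libraries, 1 in each group; whether these came from the same culture is not stated. After group means were removed, the 72 same-passage pairs had a mean correlation of 0.31 (from -0.09 to 0.7, 66 of them over 0.1), against -0.03 for the other 792 pairs.

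The gene lists, the naming rule, the tests and most alternatives were fixed before the data were examined: RLE size factors, library totals only, no filter on low counts, a mean of at least 5 CPM, DESeq2 1.42.0, the passage number as a replicate block or as a linear term, only the 2 groups compared, glmTreat with a minimum fold of 1.5, and each passage left out in turn. Added later were counts summed over the 4 libraries of a passage, fits without passages 1 and 19, a fit without the shallowest library (urea, passage 8), and other window sizes for runs of genes. The genes named are those with the 2 highest and the 2 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 5 CPM over the groups compared and the same direction in all 12 same-passage pairs. The rule was fixed with 6 or 5 genes per direction and was shortened because the identifiers have no symbols.

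Gene groups were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and at an estimated one. For runs of genes, log2 fold changes were turned into normal scores, averaged over windows of 8 consecutive tested genes and set against 1000 shuffled gene orders; a run passed where its mean lay beyond the 95% point of the shuffled extremes over the genome. Measures with 1 value per library were compared by two-sided permutation tests with 100000 resamples. Overlaps between solutes were set beside the overlap of independent lists, beside 20 simulations of unchanged groups against the shared controls, and beside contrasts with separate parts of the controls.

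The tests were tested on simulated data drawn from the real means, library sizes and dispersions of the 12654 genes, with 200 genes changed. In the real data 70.7% of genes were called for NaCl and 52.3% for urea. The simulated rates therefore do not show how scaling and false calls behave when most genes change. In the NaCl comparison 74.6% of genes changed 1.5-fold, 91% of those changed 2-fold and 98.5% of those changed 4-fold were called, with 10 calls among unchanged genes. In the comparison of NaCl with raffinose these were 80.6%, 92.5% and 100%, with 10 calls among unchanged genes. A term for passage recovered 58.2% of simulated slopes of 0.25 (log2 per 10 passages) with 48 libraries and 46.3% with counts summed per passage. Passage effects other than a slope were simulated separately, without slopes. These rates therefore do not show how much power summing costs where passages differ, as they do here.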

Results

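Gene expression was measured by RNA sequencing in MDCK I cells, a canine kidney epithelial line, after 24 h in control medium or in medium made hyperosmotic with NaCl, raffinose or urea. The stated purpose was to follow membrane transporters, drug transporters and pathways under hyperosmotic stress. Each group held 12 libraries, 1 at each of 12 cell passages. Counted reads per library, in megareads (M), had a median of 10.24 M in control (6.08 to 16.06), 11.92 M after NaCl (6.77 to 14.4), 10.12 M after raffinose (6.6 to 16.16) and 10.3 M after urea (3.92 to 15). Genes are given by Ensembl identifier with CanFam3.1 positions; levels are mean CPM ± SD with n = 12 per group, and changes are log2 fold changes ± SE with edgeR's adjusted p.

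The libraries separated by solute. The first principal component, with 60.4% of the variance of log2 CPM, parted all 24 NaCl and raffinose libraries from all 24 control and urea libraries, and the second, with 10.9%, parted urea from control. Group accounted for 72% of the variance and passage for 13.8%.

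**Figure D1:**
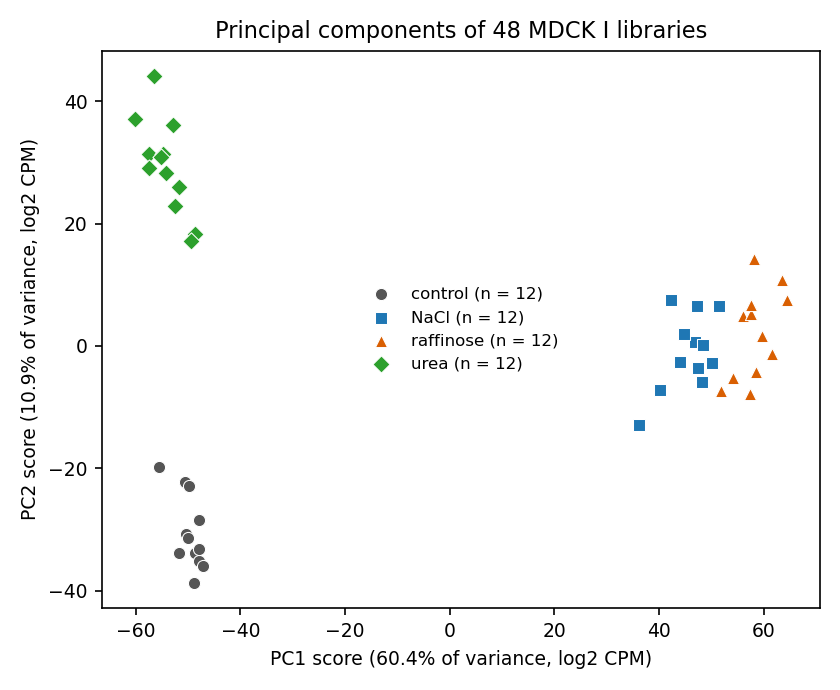
Scores of the 48 libraries on the first and second principal component of log2 CPM (12 libraries per group, 1 point each, axes in score units with the percent of variance). NaCl and raffinose libraries lie on the right, control and urea libraries on the left, and urea lies above control on the second component.

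NaCl changed 8949 of 12654 tested genes (70.7%): 4375 rose and 4574 fell, and 1243 of these rose and 991 fell by at least 2-fold. A pair of genes adjacent in the annotation of chromosome 6 had the highest changes among genes that met the naming rule. ENSCAFG00000032573 (7150741 to 7154682, minus strand, 3 exons) went from 0.0763 ± 0.20 CPM, with reads in 3 of 12 control libraries, to 229.5 ± 88.5 CPM, a log2 fold change of 11.11 ± 0.41 (adjusted p = 1.81e-29). The control library of passage 4, at 0.695 CPM, gave 75.9% of its control sum; the control mean was 0.0201 CPM without that library, and the log2 fold change 12.71 without passage 4. ENSCAFG00000013396 (7167263 to 7179455, minus strand, 4 exons) rose by 9.80 ± 0.34. The largest falls under that rule were in ENSCAFG00000012368 (chromosome 27, 26348490 to 26396959, 15 exons), from 11.0 ± 7.7 to 0.157 ± 0.18 CPM, and in ENSCAFG00000005437 (chromosome 21, 23345710 to 23393624, 14 exons), from 38.4 ± 8.4 to 0.672 ± 0.47 CPM, with log2 fold changes of -6.15 ± 0.48 and -5.85 ± 0.29. All 4 moved the same way in all 12 same-passage pairs, which the naming rule required. From at most 3 reads over all 12 controls, 15 genes rose to a mean of at least 1 CPM. Between the mean profiles of control and NaCl, 19.2% of all counts moved to other genes, against 4% between separate sets of control libraries and 10.3% after urea. Of the called genes 48.9% were higher under TMM and 34.5% when libraries were scaled by their totals only, which put the median of all genes at -0.19 and the 2-fold changes at 998 up and 1391 down.

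Raffinose changed 9482 genes (74.9%), with 4648 higher and 4834 lower, of which 1532 rose and 1282 fell by at least 2-fold. The same chromosome 6 pair led: ENSCAFG00000032573 reached 180.5 ± 47.8 CPM (log2 fold change 10.76 ± 0.41, adjusted p = 5.34e-29) and ENSCAFG00000013396 reached 73.1 ± 20.8 CPM from 0.0812 ± 0.092 (9.56 ± 0.34). The control library of passage 4, with 75.9% of the control sum of ENSCAFG00000032573, weighs on this fold change too. ENSCAFG00000005437 fell to 0.49 ± 0.33 CPM (-6.36 ± 0.31) and ENSCAFG00000012368 to 0.186 ± 0.13 CPM (-5.83 ± 0.48). As after NaCl, 15 genes rose from at most 3 reads over the controls to a mean of at least 1 CPM, and 33 genes rose from under 0.5 CPM to 5 CPM or more, against 19 after NaCl and 1 after urea. With library totals only, 33.4% of the called genes were higher in place of 49%, 1150 rose and 1954 fell by at least 2-fold, and the median of all genes was -0.25.

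Urea changed 6620 genes (52.3%), 3463 upward and 3157 downward, and the changes were smaller: 345 rose and 606 fell by at least 2-fold. The SD of the log2 fold changes over all genes was 0.579, against 0.985 for NaCl and 1.10 for raffinose. ENSCAFG00000015180 (chromosome 7, 28956363 to 28997731, 18 exons) rose from 0.939 ± 1.0 to 23.6 ± 18 CPM (4.57 ± 0.44, adjusted p = 8.03e-13), and it also rose after NaCl (5.21 ± 0.43) and raffinose (4.91 ± 0.43). ENSCAFG00000003461 (chromosome 10, 69288237 to 69293771, 8 exons) rose from 2.88 ± 1.9 to 28.3 ± 14 CPM (3.32 ± 0.26), while it fell after NaCl (-1.92 ± 0.35) and raffinose (-1.50 ± 0.34). ENSCAFG00000006902 (chromosome 1, 116938234 to 116947100, 7 exons) fell from 608.8 ± 163 to 36.4 ± 16 CPM (-4.06 ± 0.21), and ENSCAFG00000005437 fell here too (-3.67 ± 0.24). Of the called genes 52.3% were higher under TMM and 40.1% with library totals only; the latter put the median of all genes at -0.05.

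**Figure D2:**
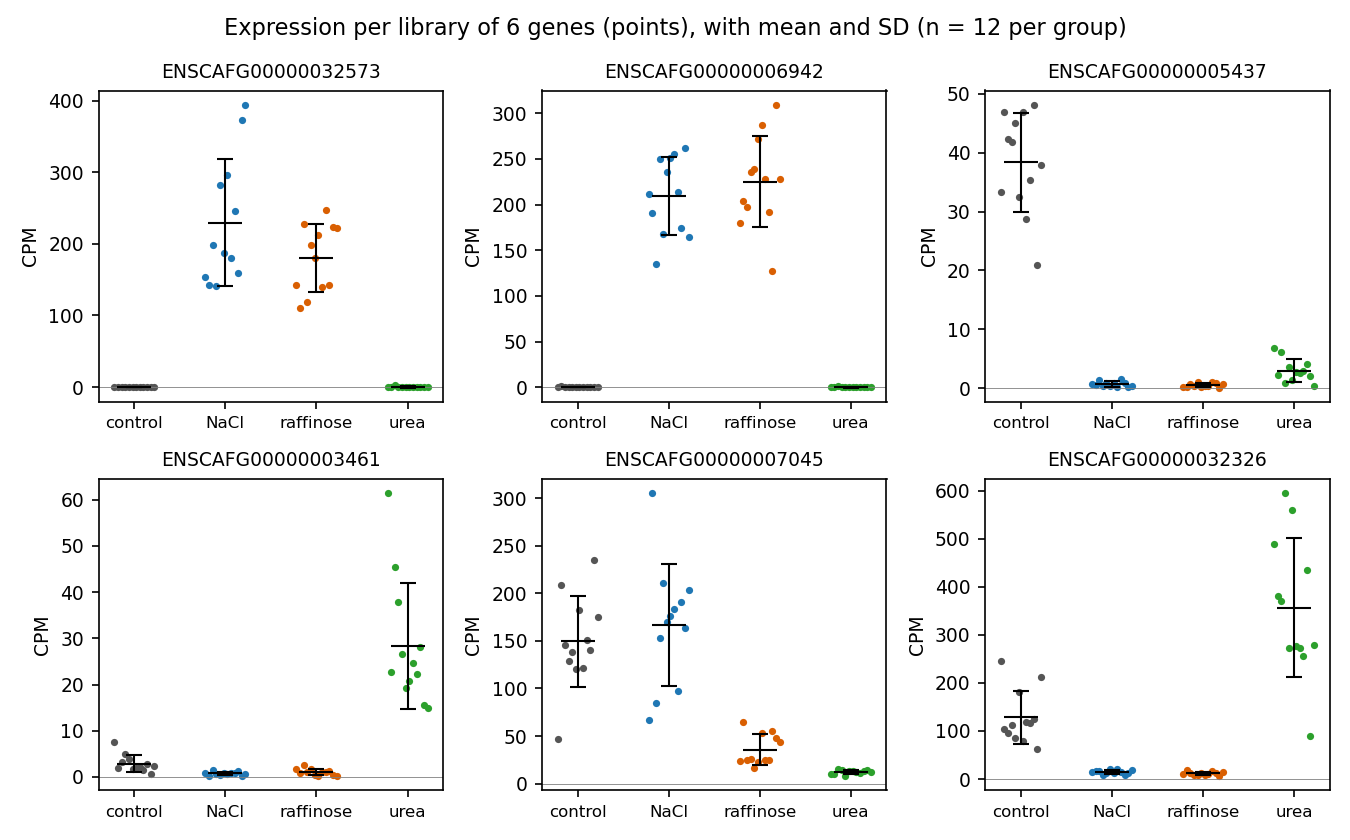
Expression in CPM (y axis, linear) of 6 genes in each library (points) by group (x axis), with the mean and SD of 12 libraries as bars. ENSCAFG00000032573 and ENSCAFG00000006942 lie near 0 in control and urea and above 100 CPM after NaCl and raffinose, ENSCAFG00000005437 falls with every solute, and ENSCAFG00000003461 and ENSCAFG00000032326 are highest after urea.

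NaCl and raffinose, which share the osmolality and differ in the solute, gave nearly the same profile. The direct test between them called 1948 genes (15.4%), 939 higher after NaCl and 1009 higher after raffinose, 22 and 43 of these by at least 2-fold among the tested genes. ENSCAFG00000007045 (chromosome 24, 21094771 to 21096390, 3 exons) had 167.1 ± 64 CPM after NaCl, against 149.6 ± 48 in control, and had 35.6 ± 16 CPM after raffinose and 12.3 ± 2.0 after urea. Its difference between NaCl and raffinose was 2.22 ± 0.21 (adjusted p = 1.22e-10). ENSCAFG00000033956 (chromosome 17, 5956896 to 5958887) was also higher after NaCl (1.36 ± 0.25, adjusted p = 0.000126), and did not pass against a minimum fold of 1.5 (adjusted p = 0.171). ENSCAFG00000030721 (chromosome 12, 71801379 to 71809983) reached 7.67 ± 3.8 CPM after NaCl and 24.1 ± 17 after raffinose from 0.598 ± 0.38, a difference of -1.65 ± 0.23, and ENSCAFG00000008335 (chromosome 32, 133974 to 140832) differed by -1.64 ± 0.22. With passage as a replicate block the count rose to 3595, and against that minimum fold it fell to 14. Of the called genes 48.2% were higher after NaCl under TMM and 71.1% with library totals only.

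NaCl and urea differed in 9183 genes (72.6%), 4519 higher after NaCl and 4664 higher after urea, and raffinose and urea in 9614 (76%), 4761 and 4853. ENSCAFG00000006942 (chromosome 15, 40179872 to 40239634, 15 exons) had 209.4 ± 42 CPM after NaCl and 224.9 ± 50 after raffinose, against 0.267 ± 0.41 in control and 0.208 ± 0.51 after urea. Its differences from urea were 9.88 ± 0.32 for NaCl and 9.98 ± 0.32 for raffinose, and 11.41 and 11.48 without passage 5. Single libraries carried these low levels: control at passage 4 had 1.46 CPM and urea at passage 5 had 1.77, and without these the means were 0.159 and 0.0657 CPM. ENSCAFG00000015756 (chromosome 27, 42269697 to 42296182, 16 exons) went from 5.69 ± 4.1 CPM in control to 1542 ± 237 after NaCl and 1939 ± 319 after raffinose, with 3.13 ± 5.7 after urea (raffinose against urea 9.23 ± 0.45, adjusted p = 7.23e-25). Urea at passage 5 had 20.5 CPM; without that library the urea mean was 1.55, and without passage 5 the difference from raffinose was 10.24. The same urea library was the highest of its group for the chromosome 6 pair, at 3.17 CPM for ENSCAFG00000032573 and 1.49 for ENSCAFG00000013396. In the other direction, ENSCAFG00000032326 (chromosome 7, 43480708 to 43482461) had 356.2 ± 145 CPM after urea, 128.3 ± 56 in control, 14.9 ± 4.3 after NaCl and 11.5 ± 3.6 after raffinose. ENSCAFG00000003461 differed from urea by -5.24 ± 0.31 for NaCl and by -4.82 ± 0.31 for raffinose. With library totals only the median of all genes was -0.10 for NaCl against urea and -0.17 for raffinose against urea. For raffinose and urea, 49.5% of the called genes were higher after raffinose under TMM and 38.8% with library totals only.

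Genes were sorted into shapes of response by rules on which comparisons passed and in which direction, and 4597 tested genes met none of these rules. The medians given for a shape largely reflect this choice, since its genes were selected by the same comparisons. In 4602 genes NaCl and raffinose acted the same way and both differed from urea in that direction (2335 up, 2267 down); their median absolute log2 fold change was 0.74 after NaCl, 0.87 after raffinose and 0.15 after urea. Of these 4602 genes, 1218 were also called the same way with urea. In 1891 other genes urea changed the level, and moved it further that way than both other solutes (945 up, 946 down). Their medians were 0.14 after NaCl, 0.17 after raffinose and 0.58 after urea. In 1564 more, urea acted opposite to NaCl and raffinose (849 up with urea, 715 down). Over all tested genes, 2925 changed the same way with all 3 solutes, 1502 up and 1423 down under TMM, and 905 up and 2170 down with library totals only.

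Of the 8266 genes called for both NaCl and raffinose, 8256 moved the same way (99.9%), where independent lists would share 1607 up and 1747 down. For NaCl and urea this was 3153 of 4877 (64.7%), against 1197 up and 1141 down. Fold changes correlated across genes at r = 0.975 for NaCl with raffinose, 0.206 for NaCl with urea and 0.202 for raffinose with urea; genes are not independent replicates. Unchanged groups simulated against the same controls gave r of 0.493, 0.493 and 0.491 and 0 genes called in the same direction in both (20 simulations). The covariances were 1.06, 0.117 and 0.129, against 0.0085 for the simulated groups, a difference of 1.051, 0.109 and 0.121. With a separate set of controls for each solute of a pair (10 divisions of the controls), 99.8%, 65% and 63.9% of shared calls had the same direction, with r of 0.952, 0.187 and 0.186. Genes moved the same way by all 3 solutes numbered 876 for 3 independent lists and 0 in the simulations. NaCl and raffinose were nearly 1 list, so the 876 does not measure what urea shared with them. With a separate set of 4 controls for each solute (10 divisions), genes moved the same way by all 3 numbered 1757 on average (1652 to 1876). The simulated groups had no change, so 0 calls were near given, here and for the pairs. With 4 controls a contrast also has less power, so the fall from 2925 to 1757 does not measure what shared controls add.

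**Figure D3:**
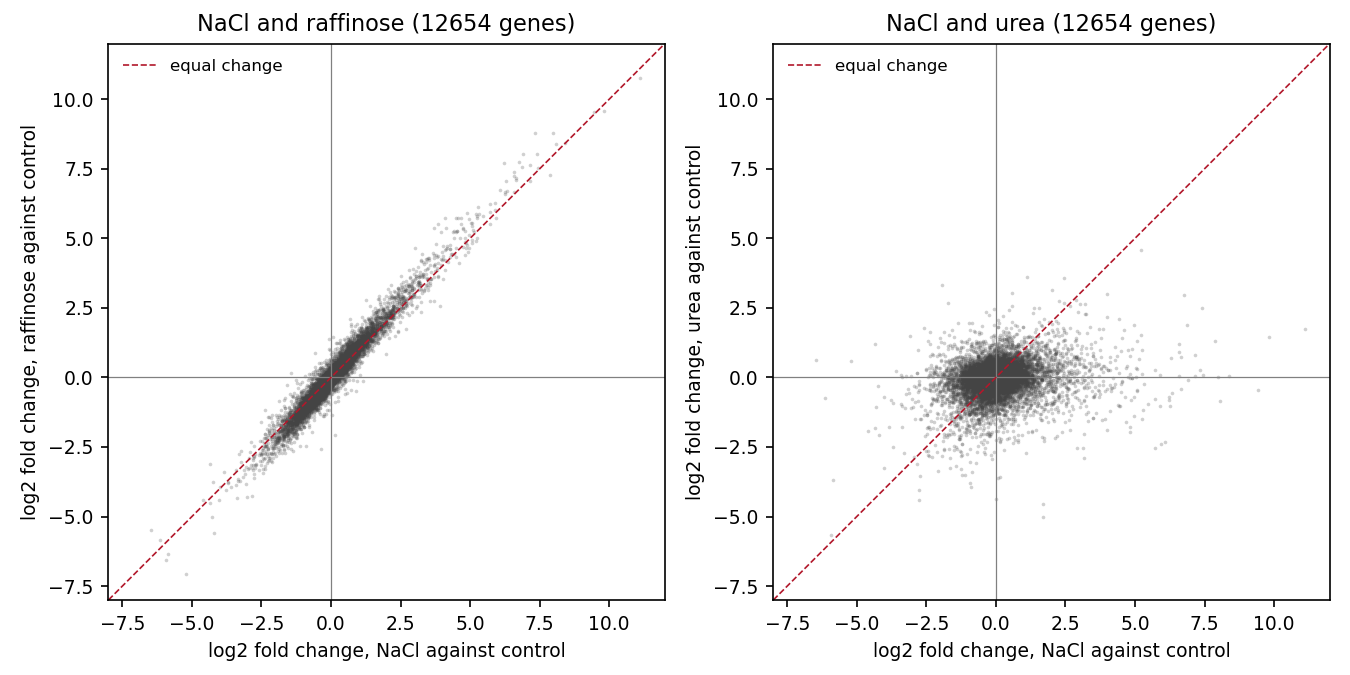
Log2 fold changes against control of 12654 genes (1 point each), with NaCl on both x axes and raffinose (left) or urea (right) on the y axes; the dashed line marks equal change. NaCl and raffinose lie along the line (r = 0.975), and urea spreads around 0 over the range of NaCl changes (r = 0.206).

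Neighbouring genes changed together in runs along the chromosomes. On chromosome 18 from 45696392 to 46473960, 14 of 15 tested genes fell and 1 rose after NaCl (median log2 fold change -1.35); 14 fell after raffinose (-1.15) and 12 after urea (-0.73). On chromosome 2 from 59138554 to 59801856, 10 of 12 rose after NaCl (1.64) and 9 after raffinose (1.86), while 5 rose and 1 fell after urea (0.12). On chromosome 3 from 56729184 to 57464239 all 8 rose after NaCl (1.69) and raffinose (1.71), and 1 rose and 5 fell after urea (-0.36). On chromosome 27 from 2080744 to 2883787, where NaCl lay below urea in 12 of 14 genes, 10 fell after NaCl and 11 after raffinose, with 2 that rose in each case, while 10 rose and 1 fell after urea. A run that rose with urea lay on chromosome 2 from 6941688 to 7897377, where 7 of 8 genes rose after each of the solutes (medians 1.66 for NaCl, 1.44 for raffinose and 0.88 for urea). In all, 9 runs passed for NaCl, 8 for raffinose and 4 for urea against shuffled gene orders. With windows of 6 and 12 genes, 6 and 7 of the 9 NaCl runs were found again, 4 and 5 of the 8 for raffinose, and 2 and 2 of the 4 for urea; the runs described here on chromosomes 2, 3, 18 and 27 were found with both sizes in the comparison they are given for.

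**Figure D4:**
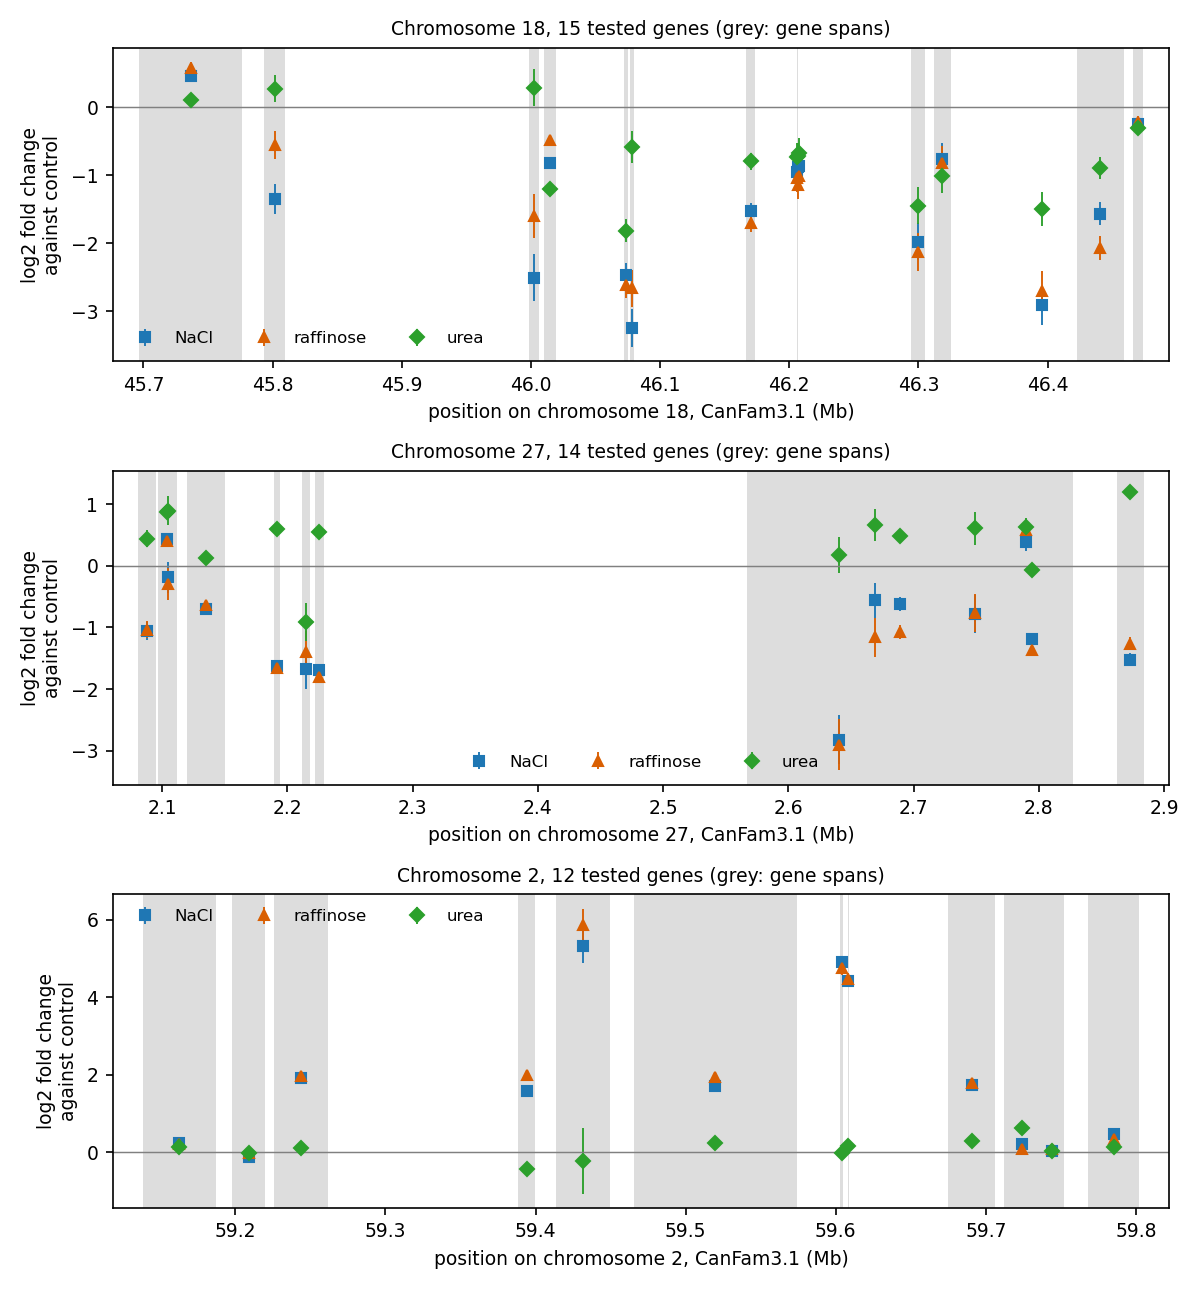
Log2 fold changes against control (y axis, points with SE bars) of the tested genes along 3 runs on chromosomes 18, 27 and 2 (x axis, CanFam3.1 position in Mb), for NaCl, raffinose and urea; grey bands are gene spans. Most genes of the chromosome 18 run fall with each solute, those of the chromosome 27 run mostly fall with NaCl and raffinose and rise with urea, and those of the chromosome 2 run rise with NaCl and raffinose.

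Larger groups of the annotation did not pass as sets at the preset correlation, which does not show that they were unchanged. Camera called 0 of 43 groups (39 chromosomes, the mitochondrial genome, genes of a single exon, and the shortest and longest gene spans) in each of the 6 comparisons, with 0 or 1 at an unadjusted p under 0.05. With an estimated correlation, chromosome 10 passed for raffinose against urea alone (211 of 462 genes higher, 145 lower, adjusted p = 0.0223 with an estimated correlation). Of 31 tested genes of the mitochondrial genome, 6 rose and 5 fell after NaCl, 10 and 4 after raffinose, and 8 and 5 after urea. With p adjusted over these genes alone, 0 rose and 3 fell after NaCl, 8 and 4 after raffinose, and 8 and 5 after urea. Of the 37 mitochondrial genes in the annotation, 22 are under 100 bases long, and some of the calls are of such genes. How well libraries of polyadenylated RNA measure them was not tested. The mitochondrial gene at 14183 to 15322 fell after NaCl (-0.73, adjusted p = 4.13e-09) and raffinose (-0.64, adjusted p = 9.41e-08) and rose after urea (0.36, adjusted p = 0.00175); it was singled out after its values were seen. Mitochondrial reads made up 5.01 ± 0.59% of counts in control, 4.74 ± 0.76% after NaCl, 4.77 ± 0.71% after raffinose and 5.4 ± 0.68% after urea, and no pair of groups passed after adjustment (6 two-sided permutation tests; NaCl against urea, lower in 9 of 12 pairs, p = 0.0336, adjusted p = 0.107).

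Most calls for a trend with passage number were lost once the libraries of a passage were combined, and permuted passage numbers gave as many calls in 5 of 40 assignments, the real one included. With 48 libraries, 1011 genes rose and 1037 fell with passage (2048 in all, median slope 0.23 log2 units per 10 passages in absolute size). With counts summed over the 4 libraries of a passage, which leaves 12 samples, 8 genes passed; 2 of 40 assignments, the real one included, gave as many, with 14 in the other. Without passage 1 the count with the remaining libraries was 1100, and without passage 5 it was 1360. ENSCAFG00000006491 (chromosome 27, 904661 to 926708, 30 exons) had a slope of 1.28 ± 0.21, with 27.5 CPM at passage 1, 111 at passage 4, 21.3 at passage 13 and 174 at passage 19, with an adjusted p of 3.14e-05 from edgeR; with summed counts the slope was 1.24 and the adjusted p 0.183, and without passages 1 and 19 the slope was 1.13. ENSCAFG00000015233 (chromosome 3, 64230065 to 64362347, 26 exons) had a slope of -1.30 ± 0.14 that passed with summed counts as well (-1.30, adjusted p = 0.04) and was -0.76 without passages 1 and 19. ENSCAFG00000009926 (chromosome 27, 13280495 to 13420864, 52 exons) had a slope of -1.56 ± 0.21, with 35.5 CPM at passage 1. Without passage 1 it was -0.37 ± 0.22 (adjusted p = 0.302), without passage 19 -1.54 ± 0.25, without both -0.08, and with summed counts -1.49 (adjusted p = 0.123). ENSCAFG00000028460, on an unplaced scaffold, had a slope of 1.02 ± 0.32 (adjusted p = 0.0222), of 1.07 with summed counts (adjusted p = 0.206), of 1.14 ± 0.39 without passage 1 (adjusted p = 0.0566) and of 1.40 without passages 1 and 19. Its highest levels were in single libraries, 126 CPM after NaCl at passage 13 and 97.6 after urea at passage 14. The edgeR test called 0 genes whose response to a solute depended on passage, with 442 at an unadjusted p under 0.05 of 12654 tested; DESeq2 called 2, the fit with passage as a replicate block called 13, and edgeR without passage 16 called 1.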

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

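The grouping of genes by their shape of response and the comparison by how many libraries stay in their real groups were chosen only after the result was seen.

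In 1564 genes the effect of urea against control was opposite to that of both NaCl and raffinose against the same controls. The number that independent lists would give was not computed for this set, so its size cannot be read as an excess. Genes moved the same way by all 3 solutes were more, 2925. For these, 3 independent lists would give 876, but NaCl and raffinose were not independent of each other (99.9% of shared calls in the same direction). The 876 therefore does not measure what urea shared with them. The direct tests of urea against NaCl and against raffinose passed in all of the 1564 genes, which follows nearly from how the set was chosen and adds no support. Of the 1564 genes, 849 rose with urea and fell with the other solutes, and 715 fell with urea and rose with the others. Their median absolute log2 fold change was 0.59 after NaCl, 0.68 after raffinose and 0.41 after urea, and 383, 490 and 188 of them changed by at least 2-fold. Against a minimum fold of 1.5 the set shrank to 99. ENSCAFG00000003461 on chromosome 10 is in the set, with log2 fold changes of 3.32 after urea, -1.92 after NaCl and -1.50 after raffinose, and so is ENSCAFG00000032326 on chromosome 7, with 1.47, -3.10 and -3.48.

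Other divisions of the same libraries did not give counts as large as the real groups. With 100 splits this argues against a chance division as the source of the totals, and says nothing about single genes. Splits that mix the groups put the group differences into the spread, so low counts there do not show how many real calls are false. Of 100 splits of the 24 libraries of a comparison, the real one included, 1 gave as many genes in each of the 6 comparisons. For NaCl the real split of 24 libraries called 8706 genes and the highest other 5997; for raffinose these were 8992 and 8118, for urea 6414 and 3199, for NaCl against raffinose 1717 and 6, for NaCl against urea 8849 and 7854, and for raffinose against urea 9029 and 3. For NaCl, raffinose, urea, and NaCl against urea, the highest other value came from a split that parts all 12 passage pairs. These splits leave 20, 22, 20 and 22 of the 24 libraries in their real groups. For NaCl against urea a freely drawn split with 20 in place gave 6311. Among splits with fewer than 20 in place the highest were 1, 0, 0 and 11. Of 100 regroupings of all 48 libraries, 1, the real one, gave as many genes changed the same way by all 3 solutes (2925), and the highest other was 0. Regrouped libraries mix the groups too, so 0 was near given and says nothing about how far the solutes share genes.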

How the results depend on the processing

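The fits with counts summed per passage, without passages 1 and 19, without the shallowest urea library, with other window sizes and with other set tests were chosen only after the data were seen.

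Of 249 alternatives to the 12 counts of genes, 231 stayed within 1.5 times the count as reported. The balance of rises and falls was less stable: of 170 alternatives to 8 of these counts, 30 turned the majority from up to down or back. With library totals only, urea went from 3463 up and 3157 down to 2593 and 3869, NaCl against raffinose from 939 and 1009 to 1542 and 628, and genes changed by all 3 from 1502 and 1423 to 905 and 2170. Of 501 alternatives to the 24 log2 fold changes of named genes, 500 kept their direction and their side of the threshold. The naming rule picked the most extreme changes with 1 direction in all 12 pairs, so this is largely given by the choice. ENSCAFG00000033956 in NaCl against raffinose lost the call against a minimum fold of 1.5 (adjusted p = 0.171, the other alternatives from 8.46e-08 to 0.000716).

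These are totals; the numbers of called genes that changed by at least 2-fold depended more on the low count filter and, for their balance, on scaling. Without it, 2412 rose and 1535 fell after NaCl, 3045 and 1901 after raffinose, and 677 and 1081 after urea, and 47 were higher after NaCl and 156 after raffinose in the direct test. At 5 CPM or more on average these were 757 and 641, 964 and 873, 186 and 315, and 11 and 16.

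Testing against a minimum fold of 1.5, a stricter question by construction, left 3108 genes for NaCl, 3969 for raffinose, 1165 for urea, 14 for NaCl against raffinose, 3497 for NaCl against urea and 4152 for raffinose against urea. It left 369 genes changed the same way by all 3 solutes, 1930 changed alike by NaCl and raffinose and more than by urea, 412 changed by urea apart from the others, and 99 in which urea was opposite. With passage as a replicate block, NaCl against raffinose had 3595 genes, and 13 genes had a response that depended on passage; the block moved none of the other counts by over 1.5 times. DESeq2 called 2 genes for that dependence. For the trend with passage, summed counts gave 8 genes and the fit without passages 1 and 19 gave 858. The cause of the changes under the block and under DESeq2 was not tested.

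With 1 passage left out of all groups, or the shallowest urea library alone, the counts ran from 8644 to 8978 for NaCl, 9238 to 9510 for raffinose, 6216 to 6538 for urea, 1529 to 1936 for NaCl against raffinose, 8923 to 9133 for NaCl against urea and 9366 to 9577 for raffinose against urea. They ran from 2729 to 2896 for genes changed the same way by all 3, 4498 to 4665 for NaCl and raffinose alike, 1814 to 1903 for urea apart, and 1373 to 1545 for urea opposite. With 1 passage left out the trend with passage ran from 1100 (without passage 1) to 2745 (without passage 16), with 1360 without passage 5, and dependence of the response on passage from 0 to 1 (without passage 16).

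Runs of neighbouring genes for raffinose numbered 5 with windows of 12 genes in place of 8 with windows of 8. The lower number of genes detected after urea did not pass without thinning (-289 genes, adjusted p = 0.222). The shallowest library, urea at passage 8, had 3.92 M reads, which limits what is seen of genes under 1 CPM there.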

Other observations

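The tests of library depth, of shared promoters and of overlapping exons, the share that a uniform rise of low genes would give, the comparison of the median low gene with the summed counts, and the comparison of the count without passages 1 and 19 with permuted passages were chosen only after the result was seen.

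The share of genes that rose after NaCl and raffinose was higher among genes of longer span, but neither the longest nor the shortest genes passed as a set. With genes in 5 groups of equal size by span, from a median of 1.6 kb to one of 112.3 kb, the share that rose went from 29.3% to 41% after NaCl and from 31.1% to 44.1% after raffinose, and the share that fell went from 36.5% to 32.5% and from 39.2% to 34.5%. After urea the shares that rose were 20.3%, 29.1%, 30.8%, 31% and 25.7%. Camera called neither the longest genes (adjusted p = 0.828 for NaCl and 0.924 for raffinose) nor the shortest (0.845 and 0.924). With library totals only their median was -0.11 for NaCl and -0.15 for raffinose, against -0.19 and -0.25 for all genes. The 10 most abundant genes of a library took 7.42 ± 0.68% of counts after raffinose and 6.76 ± 0.54% in control (n = 12, higher in 9 of 12 pairs, two-sided permutation test, adjusted p = 0.0352).

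Adjacent genes changed together: the correlation of their log2 fold changes, across 12500 adjacent pairs that are not independent replicates, was 0.183 for NaCl, 0.175 for raffinose and 0.13 for urea, against highest values of 0.029, 0.026 and 0.028 in 1000 shuffled gene orders (p = 0.001, the smallest they can give). Transcripts running from a gene of a pair into its partner cannot be the whole source, because they would not join diverging pairs. Diverging pairs had correlations of 0.246, 0.237 and 0.152, above the highest of the shuffled orders (0.052, 0.06 and 0.051). These values cover only transcripts that start within the pair. Shared promoters cannot be the whole source either, because diverging pairs over 5 kb apart had correlations of 0.221, 0.205 and 0.106 (highest shuffled 0.058, 0.069 and 0.065). Nor can overlapping exons counted without strand, because pairs 5 to 100 kb apart, which do not overlap in the annotation, had 0.19, 0.179 and 0.126 (highest shuffled 0.038, 0.043 and 0.04). Pairs that overlap or lie under 5 kb apart had more, 0.27, 0.262 and 0.215, so both may add to it. GC content shared over long regions is argued against as the whole source by distance: genes 10 apart had correlations of 0.002, 0 and -0.004, and genes 20 apart 0.024, 0.021 and -0.013 (highest of shuffled orders 0.019, 0.021 and 0.027). GC content itself was not measured, so GC content shared over shorter stretches stays open, as do near-identical neighbours, as untested. Transcripts running in from a gene outside the pair stay open too. Reads were counted without strand, so such transcripts can add to both genes of a diverging pair. Shared regulation of neighbouring genes stays open beside them, as a hypothesis found on the same data.

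More genes were detected after NaCl and raffinose than in control. With every library thinned to 3.92 M reads, 14669 ± 222 genes had a read in control, 14902 ± 147 after NaCl (232.92 more, higher in 10 of 12 pairs, adjusted p = 0.00874) and 15040 ± 183 after raffinose (371 more, 12 of 12 pairs, adjusted p = 0.00074), by two-sided permutation tests with n = 12; urea had 14467 ± 117 (202 fewer than control, adjusted p = 0.0132). Depth is argued against, since the difference of 232.92 after thinning exceeded the SD of either group. A general rise of background reads stays open, since its values point both ways. Of 5756 genes under 0.5 CPM, 58.4% were above control after NaCl and 63.5% after raffinose (62.7% to 63.8% with 1 passage left out), under the bound of 65% set beforehand, and a uniform rise of these genes would have given 66.1% and 79% in simulated counts. But the median gene among them rose by 0.24 (0.21 to 0.28 with 1 passage left out) and 0.47 (0.44 to 0.50) log2 units, against 0.22 and 0.48 for their summed CPM, which is what a general rise would give, so the bound alone does not exclude it. A response of some rarely transcribed genes to NaCl and raffinose stays open beside it, as a hypothesis.

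Gene levels followed the passage number in 2048 genes with 48 libraries, but 5 of 40 assignments of the passage numbers, the real one included, gave as many (highest other 3332), so chance cannot be excluded. Counting the 4 libraries of a passage as independent is a candidate explanation that the data bear out. With summed counts 8 of the 2048 passed, though 12 samples also have less power for a real slope. In simulated data, passage effects with a set SD of 0.25 log2 units and no slope gave 754 calls with 48 libraries. The same effects gave 0 calls with summed counts. Whether the calls rest on passages 1 and 19 stays open: the count was 858 without them and 1100 without passage 1 alone, but with passage numbers permuted over the 10 passages left, 7 of 40 assignments, the real one included, gave 858 or more (highest other 1625). The bound on this count set beforehand was thus one that permuted passages reach, and the slopes of called genes without them, which correlated at 0.87 with the full ones, share 10 of the 12 passages with those by design. A dependence on passage in some genes stays open. For responses that depend on passage, edgeR called 0 genes (442 at an unadjusted p under 0.05; DESeq2 called 2 and the fit with passage as a replicate block 13). With a real count of 0, all 40 assignments give at least as many whatever the data (highest other 3), so they decide nothing. The test recovered 3% of simulated slopes of 0.25 and 80.3% of slopes of 1.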
